A study of Gallus gallus with 2 samples.

How the data were processed

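Total RNA of the MSC culture and of the IPC culture was made into small RNA libraries with the TruSeq small RNA method from a gel fraction of 16 to 40 nt, per the labels' protocols, and sequenced on an Illumina instrument. For each library the deposited file lists every distinct read sequence after adapter removal with its length and its raw read count, per the file headers. The values used are therefore deposited counts of reads per distinct sequence, without normalization. Both value columns of a file held the same count in every row, and each stated length equalled the number of letters. The trimming program, any aligner and the genome build are not given in the sources used here.

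The plan made before the data were examined was to match reads to annotated miRNA hairpins. A chicken genome sequence was not used here, so reads were instead matched to a hand-written table of 159 conserved mature miRNA sequences. The pairing of name and sequence comes from general knowledge and not from a reference read here. Names were kept where the table of chicken genes (assembly GRCg7b, used for names only) lists a miRNA gene of that name, which held for 150 sequences. Another 2 were pooled with a listed relative and 7 were left out, giving 143 counted miRNAs. The sequence table was written after the most abundant reads had been seen. miR-221-5p and miR-222b-3p were added because abundant reads had remained unmatched, and near-identical relatives (such as miR-103 with miR-107, and miR-29a with miR-29c) were pooled at that stage. miRNAs outside the table, including those specific to birds, were not counted. No coordinates are given.

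A read of 18 to 26 nt was assigned to a mature miRNA when it matched it through position 18, began within 2 nt of its 5′ end and ended within 3 nt of its 3′ end. A read that matched several went to the one with the longest match and then the smallest end offset, and ties were split equally. Mismatches beyond position 18, where nucleotides are added to miRNAs, were allowed. Members of a family that differ by 1 nucleotide, such as miR-1a and miR-1b or the let-7 miRNAs, can receive each other's misread reads, so the lower of such a pair is uncertain. This gave 16125862 miRNA reads for MSC and 3990559 for IPC, and levels were expressed as RPM, here reads per 1000000 of these. A count of 3 corresponds to 0.186 RPM in the MSC library and 0.752 RPM in the IPC library, which is taken as the limit that a count of 0 allows.

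With 1 library per cell type no test with replicates was possible, and a size rule was used. miRNAs at 10 RPM or more in either library were compared, and 1 was called higher or lower when the ratio was at least 2-fold and its exact binomial 95% interval excluded 1. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Log2 ratios were computed after adding 0.5 to each count. For a list, the median log2 ratio of its tested members was placed among the medians of 10000 random lists of the same size drawn from 4 expression classes, and intervals of a median come from 1000 Poisson draws of the counts. The miRNA names on the 22 lists were fixed before the data were examined, whereas the members that could be counted depend on the sequence table, which was written later. Lists with fewer than 3 tested members have no percentile. Both arms of a precursor, and related miRNAs of 1 family, count as separate members of a list. The random lists treat members as independent, so a percentile can overstate how far such a list stands apart.

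The miRNAs named in the report follow a rule fixed in advance: the 10 most abundant in each library, the 10 largest ratios in each direction among those at 100 RPM or more in either library, miR-375, and up to 4 members of each list with the largest ratios in each direction. It gave 79 miRNAs. miRNAs named outside it are said to have been chosen after their values were seen.

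Alternatives set in advance were scaling to all reads, TMM factors (edgeR 4.0.16 in R 4.3.3, used for scaling only), median-of-ratios factors, totals without the most abundant miRNA, no filter or a filter of 100 RPM, a pseudocount of 5, reads identical to the mature sequence, and reads with several matches left out. Further ones were chosen after seeing the data: totals without the 2 most abundant MSC miRNAs, scaling to the median miRNA, no mismatch beyond position 18, no limit on the 3′ end, and miR-221-5p and miR-222b-3p left out. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

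The assignment and the size rule were tested on simulated libraries made from these miRNAs, with 40 of the 126 tested changed. For IPC against MSC, 20 of 20 miRNAs changed 4-fold and 20 of 20 changed 3-fold were called in the right direction, and 0 of 86 unchanged ones were called. Apart from these changes both simulated libraries had the same composition, with Poisson counts and reads built from the written sequences. The test therefore says nothing about a shift of ratios by dominant miRNAs. It is equally silent on read ends that differ from the table or between libraries. The largest error of a log2 ratio was 1.1, for miR-221-5p, and the largest of the others was 0.338. The mature sequence of miR-221-5p, at 26 nt, is at the upper length limit, beyond which reads are not counted. Whether this caused its error was not tested.

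Fragments of transfer RNA and of 5.8S ribosomal RNA were counted by short sequences chosen after the most abundant reads had been seen. For coding fragments, reads of 27 nt or more were translated and matched over 8 amino acids to parts of proteins written from general knowledge, with the reversed proteins as background. The amylase and chymotrypsin parts are the human ones, so reads of the chicken genes were found only where the protein is conserved.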

Results

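Small RNA was sequenced from 2 chicken cell preparations, with 1 library for each. Mesenchymal stem cells (MSC) are stromal cells that can be grown in culture and turned into other cell types. Insulin-producing cells (IPC) had been derived from MSC in culture by a stepwise treatment. It began with 1 µM of the DNA-demethylating drug 5-azacytidine for 18 h and 0.1 mM mercaptoethanol. Activin A at 15 ng/mL was given on day 6 and retinoic acid on day 7, followed by 10 ng/mL basic fibroblast growth factor and 10 mM nicotinamide. The comparison asked which microRNAs (miRNAs, the short RNAs of about 22 nt that repress messenger RNAs) differed between the starting cells and the derived cells. The MSC library held 29312156 reads of 1097331 distinct sequences, and the IPC library held 18745322 reads of 1350775 distinct sequences. With 1 library per cell type no difference below has a replicate check, and no significance test was made. Each 95% interval covers counting error only, so every ratio compares these 2 libraries and not the cell types in general.

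By the main counting the MSC library was dominated by 2 miRNAs. miR-143-3p (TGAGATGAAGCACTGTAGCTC), a miRNA of smooth muscle and other mesenchymal cells, took 49.3% of its miRNA reads. Together with miR-21-5p (TAGCTTATCAGACTGATGTTGA), which is abundant in many cultured and stressed cells, it accounted for 78.0%. In the IPC library the same place was shared among many miRNAs. The most abundant, miR-22-3p (AAGCTGCCAGTTGAAGAACTGT), took 15.2% of its miRNA reads, and the 10 most abundant took 66.8%, against 90.1% in the MSC library. The order depends on the counting rule. When exact mature reads alone were counted, miR-21-5p ranked first in the MSC library with 20.5% of such reads, followed by let-7f with 14.5%, let-7a with 12.2% and miR-148a-3p with 9.49%, and miR-143-3p held 5.25%. In the IPC library miR-22-3p then held 32.0% and miR-375-3p 7.18%, and miR-26a-5p, of whose reads 3.86% were exact, held 1.04%.

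After miR-143-3p and miR-21-5p, the most abundant miRNAs of the MSC library were let-7f at 25451, let-7a at 22048, miR-30a-5p at 19837 and miR-148a-3p at 16523 RPM (reads per 1000000 miRNA reads). They were followed by miR-30d-5p at 10568, miR-103 and miR-107, counted together, at 9398, let-7k at 9290.4 and the pooled miR-146a/c-5p at 8572 RPM. In the IPC library, miR-22-3p at 151924 RPM was followed by miR-26a-5p at 123557, miR-21-5p at 114487 and miR-375-3p at 103013 RPM. The remainder of its 10 most abundant were miR-100-5p at 39131, miR-125b-5p at 33401, miR-30d-5p at 27109, miR-191-5p at 26669.9, miR-181a-5p at 26091 and miR-148a-3p at 22454 RPM.

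miR-375-3p (TTTGTTCGTTCGGCTCGCGTTA), the best-known miRNA of pancreatic islet cells, was counted 21 times in the MSC library and 411080 times in the IPC library. Its level went from 1.30 RPM to 103013 RPM, a ratio of 79104 with an interval of 51748 to 127791. It was the largest ratio of the 126 miRNAs that reached 10 RPM in either library. miR-216a-5p (TAATCTCAGCTGGCAACTGTGA), a miRNA known from the pancreas, had 0 reads in the MSC library, which allows up to 0.186 RPM, and 757 reads or 189.7 RPM in the IPC library. Against that limit of 3 counts it was at least 1019.7-fold higher. Its neighbour in vertebrate genomes, miR-216b-5p, was at 0.186 RPM from 3 reads in the MSC library and at 362 RPM in the IPC library, a ratio of 1946 (665 to 9449).

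Further miRNAs with the largest ratios in the IPC library are known from several cell types. miR-222b-3p was 1692-fold higher (1127 to 2670.4), from 1.43 to 2413 RPM. miR-142-5p, a miRNA of blood-forming cells, was 1116-fold higher (940.5 to 1336), from 8.12 to 9069 RPM. miR-147-3p, which is induced in immune responses, was 547-fold higher, and miR-204-5p, found in islet beta cells and in the eye, was 436-fold higher. miR-22-3p was 178-fold higher (175 to 181), miR-191-5p 150.3-fold higher, and miR-429-3p, an epithelial miRNA of the miR-200 family, 131-fold higher.

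In the other direction, miR-196-5p (TAGGTAGTTTCATGTTGTTGG), encoded within the Hox gene clusters that pattern the body axis, had 12655 reads or 785 RPM in the MSC library and 0 reads in the IPC library. A count of 0 there allows up to 0.752 RPM, the level of 3 counts, and against that limit it was at least 1044-fold lower in the IPC library. miR-1a-3p, a muscle miRNA, was 707-fold lower, with 5312 RPM in the MSC library and 7.52 RPM in the IPC library. miR-184-3p was 137-fold lower, from 3120.2 to 22.8 RPM. miR-143-3p was 48.4-fold lower, from 492898 to 10182 RPM, but 5.40-fold lower when exact mature reads alone were counted, which made up 1.62% of its MSC reads and 43.8% of its IPC reads. The 5.40-fold value is scaled to the total of exact reads, which shifts all ratios by a common factor described below. let-7k was 9.15-fold lower, miR-215-5p 7.16-fold, miR-24-3p 5.70-fold, miR-16c-5p 5.43-fold, miR-140-5p, known from cartilage, 5.33-fold and let-7c 5.01-fold lower.

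Of the 126 miRNAs, 77 were at least 2-fold higher in the IPC library with an interval excluding 1, 24 were at least 2-fold lower, and 25 met neither condition. These counts rest on scaling to the miRNA total, under which the median miRNA was itself 3.56-fold higher in the IPC library, a log2 ratio of 1.83. Scaled to that median miRNA instead, 53 were higher and 48 lower, and with trimmed-mean (TMM) scaling, which shifted every log2 ratio by -1.90, the split was 50 to 48. The median-of-ratios scaling gave 53 higher and 47 lower, scaling to all reads gave 56 and 42, and leaving the most abundant miRNA of each library out of the total gave 64 and 34. Totals without miR-143-3p and miR-21-5p, added after seeing the data, gave 49 and 49. This setting, TMM, median of ratios and the median miRNA bring the median ratio close to 1 and are called the 4 centring scalings below. All 24 lower calls were kept under each of these scalings, as were 53 of the 77 higher calls when scaled to the median miRNA. Each of these scalings lowers every ratio relative to the main one. By construction only higher calls could be lost, so the kept lower calls are no sign of greater robustness. Of the 70 miRNAs named and called here, 56 kept their call relative to the median miRNA. The other 14, all called higher, were miR-10b-5p, miR-16-5p, miR-23a/b-3p, miR-29b-3p, miR-30c-5p, miR-30d-5p, miR-34a-5p, miR-133-3p, miR-145-5p, miR-146a/c-5p, miR-210-3p, miR-301a-3p, miR-1329-5p and let-7b. The ratio of 27 miRNAs lay above 1 under 1 scaling and below 1 under another, and this is stated below wherever such a miRNA is named with a direction.

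Counting exact mature reads alone moved 73 of the 79 named ratios by over 1.5-fold. It also replaced the miRNA total with the total of exact reads, which shifts all ratios by 1 common factor. miR-148a-3p, with 87.5% of its MSC and 87.3% of its IPC reads exact, moved from a log2 ratio of 0.44 to -1.15. All ratios and calls given with exact reads thus reflect this factor as well as the ends of each miRNA's own reads. Of the 70 named miRNAs called by the main counting, 53 were called in the same direction with exact reads, 12 were not called and 5 were called in the other direction. The calls that ended were those of let-7b, let-7i, miR-10b-5p, miR-16-5p, miR-29b-3p, miR-34a-5p, miR-133-3p, miR-145-5p, miR-146a/c-5p, miR-153-3p, miR-301a-3p and miR-456-3p, and those that turned from higher to lower were of miR-30d-5p, miR-155-5p, miR-210-3p, miR-363-3p and miR-1329-5p. The turned call of miR-155-5p rests on 42 exact MSC reads and 2 exact IPC reads. miR-375-3p remained the largest ratio upward among the named miRNAs, at 20749.7-fold from 8 exact MSC reads, and miR-22-3p was 66.8-fold higher.

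**Figure D1:**
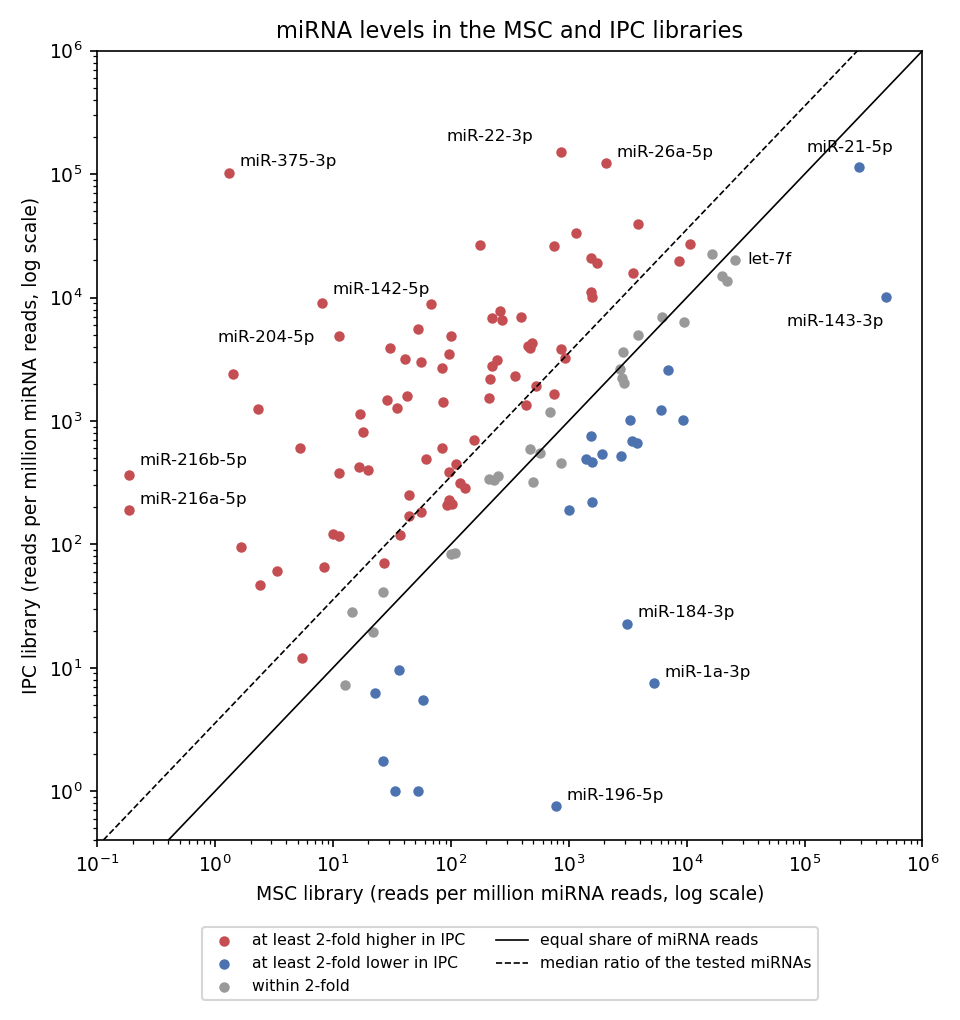
Level of each of the 126 tested miRNAs in the MSC library (x axis) and the IPC library (y axis), both in RPM on log scales. Each point is 1 miRNA with 1 library per axis and a count of 0 is drawn at the level of 3 counts. The solid line marks equal shares and the dashed line the median ratio of 3.56. miR-375-3p lies at 1.30 against 103013 RPM and miR-143-3p at 492898 against 10182 RPM.

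Among miRNAs known from islets and insulin secretion, 15 of 21 tested members were higher in the IPC library, 3 were lower and 3 were neither. Scaled to the median miRNA the counts were 10 higher, 6 lower and 5 neither. Besides miR-375-3p and miR-204-5p, the list held miR-26a-5p, which was 59.9-fold higher and 4.82-fold higher with exact mature reads. Its members went in both directions, and miR-184-3p and miR-24-3p were among the 10 largest ratios downward of the miRNAs at 100 RPM or more in either library. The list's median log2 ratio was 1.67 (1.497 to 1.85), at the 33.8th percentile of 10000 random lists of the same size matched on expression. As a whole it did not stand apart from other miRNAs, and its median was below 0 under several other scalings (-0.23 with TMM).

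The epithelial miRNAs divided within the list. Of 5 tested, 3 were higher and 2 lower, with a median log2 ratio of 6.30 at the 99.1st percentile of matched lists. miR-429-3p went from 67.3 to 8794 RPM and miR-200b-3p from 53.0 to 5595 RPM, the latter a 106-fold difference (98.7 to 113). Both belong to the miR-200 family, which maintains the epithelial state. By contrast miR-203-3p and miR-205-5p, which are known from skin and other stratified epithelia, were 10.6-fold and 3.61-fold lower, at 5.51 and 6.26 RPM in the IPC library.

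The list of mesenchymal and fibroblast miRNAs was not lower as a group. Of its 24 tested members 15 were higher, 4 lower and 5 neither. Scaled to the median miRNA the counts were 10 higher, 9 lower and 5 neither. miR-22-3p and miR-222b-3p had the largest ratios upward, miR-143-3p and miR-140-5p the largest downward. Further members among the most abundant miRNAs were miR-100-5p, 10.2-fold higher, miR-125b-5p, 29.1-fold higher, and miR-21-5p, 2.51-fold lower. The median log2 ratio was 1.71 (1.66 to 1.77), at the 55.2nd percentile of matched lists, and it was -0.19 with TMM scaling. Without miR-221-5p and miR-222b-3p, which were added to the counted miRNAs after unmatched reads had been seen, 13 of 22 were higher and the median was 1.72, at the 57.25th percentile. The reads of all members summed to 809795 RPM in the MSC library and 420882 RPM in the IPC library, a 1.92-fold lower sum that rests on miR-143-3p and miR-21-5p. The smooth muscle pair, which is processed from 1 cluster in vertebrates, came apart: miR-143-3p was lower as above, and miR-145-5p was 4.50-fold higher, from 854 to 3847 RPM. Relative to the median miRNA miR-145-5p was 1.26-fold higher and no longer called, so that the pair had 1 lower and 1 neither, and with exact mature reads it was 1.99-fold higher and not called.

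Skeletal and cardiac muscle miRNAs were higher in the MSC library. Of 5 tested, 4 were lower in the IPC library and 1 was higher, with a median log2 ratio of -4.89 at the 0.16th percentile of matched lists. The same 4 were lower relative to the median miRNA, a scaling that lowers every ratio and could not remove these calls. miR-1a-3p was the most abundant. miR-1b-3p was 52.3-fold lower and miR-206-3p, of skeletal muscle, 33.3-fold lower, each with 4 reads in the IPC library. miR-1b-3p differs from miR-1a-3p by 1 nucleotide. Its 845 MSC reads may be misread miR-1a-3p, which had 85665 there, so it may not be a separate member of the 4. The exception was miR-133-3p, at 55.7 RPM in the MSC library and 184 RPM in the IPC library, which was 3.31-fold higher by miRNA total and lower under the 4 centring scalings.

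Neural miRNAs were higher in the IPC library for 6 of 7 tested members and neither for 1, against 4 higher, 1 lower and 2 neither when scaled to the median miRNA. Their median log2 ratio was 4.26, at the 92.6th percentile. miR-153-3p, which is also expressed in endocrine cells, was 117-fold higher, miR-128-3p 49.4-fold, miR-138-5p 36.4-fold and miR-137-3p 19.4-fold. With exact mature reads miR-138-5p was 214-fold, miR-128-3p 14.9-fold and miR-137-3p 5.34-fold higher, and miR-153-3p had 2 and 4 such reads, too few to be compared. Blood cell miRNAs were higher for 5 of 5 tested members under either scaling, with a median log2 ratio of 3.39 at the 67.1st percentile. These 5 include both arms of miR-142. miR-144-3p of the same list, named after its value was seen, had 0 reads in the MSC library and 1 in the IPC library and was not tested. Next to miR-142-5p, miR-223-3p of myeloid cells was 53.7-fold higher, from 55.9 to 3003 RPM, and miR-155-5p was 10.5-fold higher by the main counting but lower when exact mature reads alone were counted (log2 ratio -3.66). That exact-read ratio of miR-155-5p rests on 42 reads in the MSC library and 2 in the IPC library. miR-451-5p of red cells was 7.96-fold higher and at 66.2 RPM in the IPC library.

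Immune response miRNAs were higher for 4 of 6 members, lower for 1 and neither for 1, with a median log2 ratio of 2.29 at the 68.7th percentile. Scaled to the median miRNA 3 were higher, 2 lower and 1 neither. Besides miR-147-3p, miR-21-3p was 51.7-fold higher, whereas miR-21-5p from the same precursor was lower. With exact mature reads, which were 3.18% of its IPC reads, miR-21-3p was 2.84-fold and miR-147-3p 82.4-fold higher. For miR-147-3p these were 2 exact reads in the MSC library and 153 in the IPC library. miR-146b-5p was at 2737 and 2659.8 RPM, but 28.9-fold lower with exact mature reads, of which it had 1259 and 32. miR-146a/c-5p was 2.29-fold higher by miRNA total and lower under every other scaling except the total without the most abundant miRNA. The endothelial miR-126 had its 5p arm 12.02-fold higher, at 120.8 RPM in the IPC library, and its 3p arm at 26.7 and 41.3 RPM. That 3p arm had 0 exact mature reads in either library. The liver miRNA miR-122 did not reach 10 RPM in either library.

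**Figure D2:**
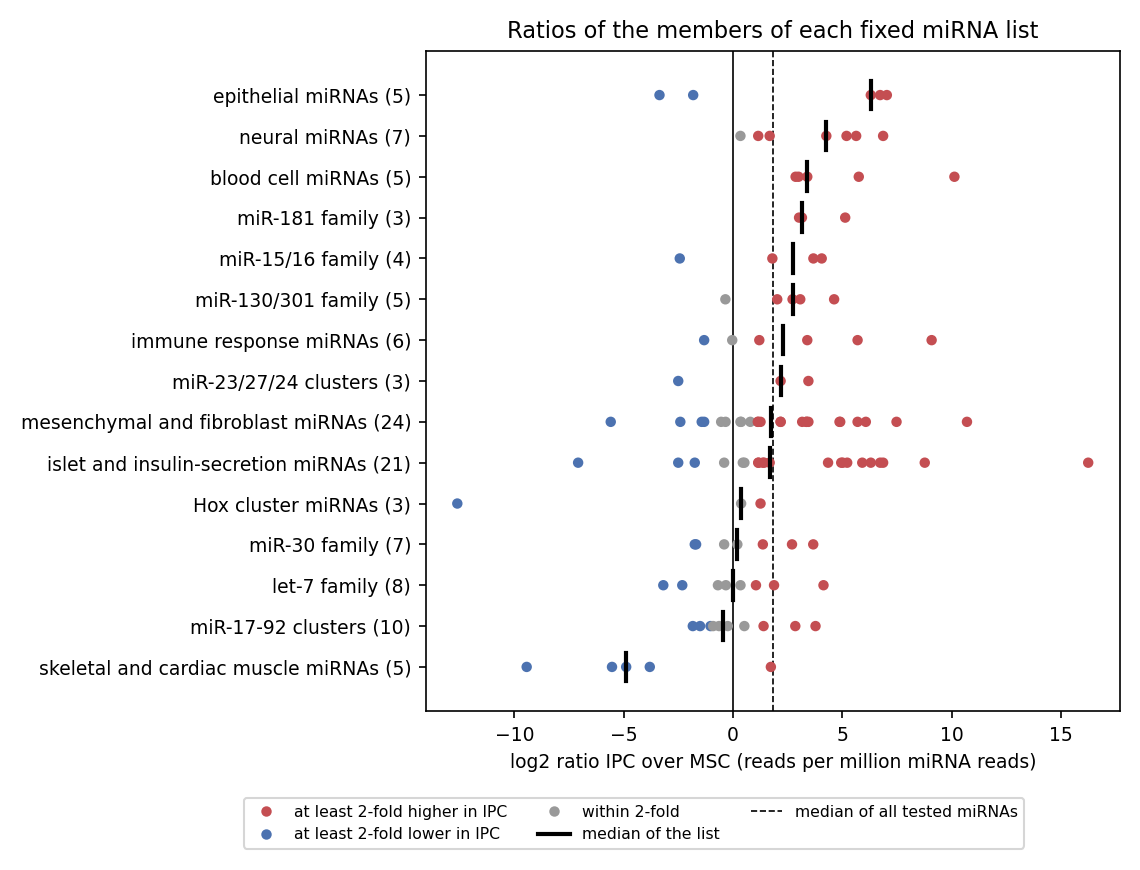
The log2 ratio of IPC over MSC in RPM (x axis) for the tested members of the 15 lists with 3 or more of them (y axis, number tested in parentheses). Points are single miRNAs coloured by call and thick bars are list medians, with 1 library per cell type. The median is 6.30 for the epithelial list and -4.89 for the muscle list, and 1.83 for all tested miRNAs (dashed line); a change of scaling moves every point by the same amount.

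The let-7 family, which accumulates as cells differentiate, did not move as 1 group by the main counting. Of 8 members 3 were higher, 2 lower and 3 neither, against 1 higher, 5 lower and 2 neither scaled to the median miRNA. let-7i was 17.5-fold higher by the main counting, though not when exact mature reads alone were counted (log2 ratio -0.13). let-7k and let-7c were lower as above. let-7b was 3.66-fold higher by miRNA total but slightly lower with TMM and with the totals without miR-143-3p and miR-21-5p. With exact mature reads let-7a was 5.14-fold, let-7f 3.89-fold, let-7k 28.2-fold and let-7c 14.8-fold lower, and neither let-7b nor let-7i was called. These values include the common shift of exact-read ratios. The family's median log2 ratio was 0.0020, at the 12.3rd percentile.

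The miR-17-92 clusters, which are tied to proliferation, had 3 members higher, 3 lower and 4 neither of 10, with a median log2 ratio of -0.45 at the 3.37th percentile. Scaled to the median miRNA 2 were higher, 7 lower and 1 neither. miR-20a-5p was 3.59-fold lower and miR-20b-5p 2.85-fold lower, while miR-92-3p was 13.6-fold higher. With exact mature reads they were 17.8-fold lower, 14.5-fold lower and 2.45-fold higher. miR-363-3p was 7.17-fold higher by the main counting and lower with exact mature reads (log2 ratio -1.29).

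Hox cluster miRNAs included 1 higher, 1 lower and 1 neither, or 2 lower and 1 neither relative to the median miRNA. Apart from miR-196-5p, miR-10a-5p was at 3845 and 4955 RPM, and miR-10b-5p was 2.38-fold higher by miRNA total but lower under every other scaling except the total without the most abundant miRNA. The median log2 ratio of the list was 0.37, at the 23.3rd percentile. The miR-30 family had 3 members higher, 2 lower and 2 neither, with a median of 0.19 at the 25.9th percentile, against 1 higher, 4 lower and 2 neither relative to the median miRNA. miR-30b-5p was 12.7-fold higher and miR-30c-5p 6.46-fold higher, and miR-30a-3p and miR-30e-3p were 3.37-fold and 3.23-fold lower. With exact mature reads these were 5.09-fold and 3.77-fold higher, and 10.0-fold and 9.67-fold lower. The share of exact reads was alike in the MSC and IPC libraries for miR-30a-3p (70.9% and 71.8%) and miR-30e-3p (84.1% and 84.7%). Their larger exact-read values thus come mostly from the common shift of exact-read ratios. By such reads miR-30a-5p, within 2-fold by the main counting, was 14.5-fold lower and miR-30d-5p 3.76-fold lower. miR-30d-5p, at 10568 and 27109 RPM, was higher by miRNA total and without the most abundant miRNA, and lower under the other scalings.

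Other families were higher in the IPC library for most members by miRNA total. All 3 tested members of the miR-181 family were higher under either scaling, led by miR-181a-5p at 34.9-fold, with miR-181b-5p at 8.85-fold and miR-181a-3p at 8.09-fold; the median was 3.15 at the 71.5th percentile. In the miR-15/16 family 3 of 4 were higher and 1 lower (2 and 1 relative to the median miRNA), with a median of 2.73 at the 66.8th percentile. miR-15a-5p was 16.6-fold higher and miR-15b/c-5p 12.7-fold higher. miR-16-5p was 3.47-fold higher by miRNA total but slightly lower under the centring scalings other than median of ratios. The family of miR-130, miR-301 and miR-454 had 4 of 5 higher and 1 neither (2 higher and 1 lower relative to the median miRNA), with a median of 2.72 at the 58.3rd percentile. miR-454-3p was 24.6-fold higher, miR-130a-3p 8.40-fold and miR-301a-3p 4.05-fold. The last was not called relative to the median miRNA (1.14-fold) or with exact mature reads (1.09-fold). miR-130b-3p was at 2847 and 2227 RPM, but 0.035% of its MSC reads and 0% of its IPC reads were exact, too few to compare.

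In the miR-23/27/24 clusters, miR-27a/b-3p was 10.9-fold and miR-23a/b-3p 4.51-fold higher and miR-24-3p was lower, with a median of 2.17 at the 65.8th percentile. Relative to the median miRNA, 1 of these 3 was higher, 1 lower and 1 neither. Both miR-29 features, known to target collagen messages, were higher by miRNA total. miR-29a/c-3p was 30.8-fold higher, from 223 to 6876 RPM, and miR-29b-3p was 2.67-fold higher but lower under the 4 centring scalings. Both tested early-embryo miRNAs were higher by miRNA total, miR-456-3p 7.39-fold and miR-1329-5p 5.72-fold, against 1 higher and 1 neither relative to the median miRNA. With exact mature reads miR-1329-5p was lower (log2 ratio -1.33) and miR-456-3p was not called (-0.37). The other counted members of this list, named after their values were seen, were nearly absent and not tested. miR-302a/b-3p had 6 reads in the MSC library and 2 in the IPC library, miR-302c-3p 2 and 0, and miR-367-3p 0 in each. miR-34a-5p was 3.83-fold higher and the hypoxia-responsive miR-210-3p 3.12-fold higher by miRNA total. miR-34a-5p was slightly lower when the totals left out miR-143-3p and miR-21-5p, and miR-210-3p was lower under the 4 centring scalings. With exact mature reads miR-210-3p was lower, at -1.94 on the log2 scale, and miR-34a-5p was not called, at -0.19.

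The RNA content of the libraries differed as well. Reads assigned to a listed miRNA made up 55.0% of the MSC library (exact binomial interval 54.996 to 55.032) and 21.3% of the IPC library (21.27 to 21.31). Reads of 21 to 23 nt, the usual length of miRNAs, were 47.2% and 34.1% of reads, and listed miRNAs accounted for 84.6% and 52.2% of that length class. Reads of 18 to 19 nt made up 1.86% of the MSC library and 21.2% of the IPC library. Fragments starting at the 5′ end of glycine transfer RNA took 13.3% of MSC reads and 0.919% of IPC reads. The longest reads were 35 nt in the MSC library and 36 nt in the IPC library, so the libraries were not read or trimmed to the same length. Any difference in library making or sequencing coincides with the cell type and cannot be separated from it here.

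**Figure D3:**
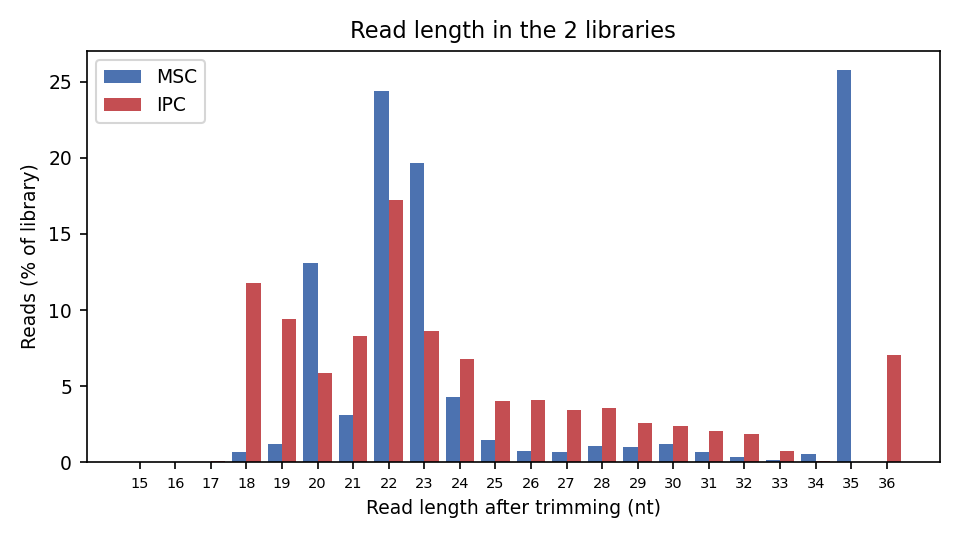
Share of reads in percent of each library (y axis) by read length in nt after adapter removal (x axis), with 1 library per cell type. Reads of 21 to 23 nt sum to 47.2% for MSC and 34.1% for IPC, and the longest class, at 35 nt for MSC and 36 nt for IPC, holds 25.7% and 7.06%.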

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

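The short RNA classes below were chosen after the reads had been seen. The test of scaling was also made after the result, whereas the tests on hormone and enzyme reads were set before those reads were counted. Holding the enzyme level against the hormone level was added after both had been seen, and by the rule set beforehand alone exocrine RNA would have been argued against. The signals were picked out because they lie outside the miRNA comparison and exceed their level in the MSC library.

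Reads containing the 5′ end of 5.8S ribosomal RNA made up 6.57% of IPC reads and 0.725% of MSC reads. A sequence that matched no RNA named here, counted by a motif picked from the IPC library itself, took 4.42% of IPC reads with 828239 reads, and 0 reads in the MSC library. Fragments from the 5′ end of glutamic acid transfer RNA were 0.901% of IPC reads and 0.469% of MSC reads.

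Reads coding for islet hormones were found in the IPC library alone: 6 for insulin, 21 for glucagon and 8 for somatostatin. The MSC library had 0 for each hormone, which at its depth allows up to 0.102 reads per 1000000 reads (3 counts). The IPC levels were 0.320 reads per 1000000 reads for insulin (0.118 to 0.697), 1.12 for glucagon and 0.427 for somatostatin. The reversed proteins matched 0 reads. Reads for beta actin, present in all cells, numbered 7426 in the MSC library and 679 in the IPC library, so the absence in the MSC library is not explained by fewer coding fragments there.

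These hormone reads bear on the pattern of miR-375-3p, the miR-200 family, and miR-216 and miR-217 being far higher in the IPC library. miR-200a-3p, 78.6-fold higher, and miR-217-5p, 57.2-fold higher, were added to this pattern after their values were seen. None of the scalings tried removed this pattern, since the lowest median log2 ratio of these miRNAs over all scalings was 5.04. Each scaling moves all miRNAs by 1 factor and these members had large ratios from the start. The outcome thus followed from their choice and is no independent support. RNA of exocrine pancreas cells stays open. Reads for amylase, trypsin and chymotrypsin reached 0.231% of those for beta actin and elongation factor 1 alpha (upper bound 0.834%), below the 10% set in advance, but that level was assumed, the hormone reads themselves reached 4.04% (upper bound 5.62%), and human sequences were used for 2 of the enzymes. Islet hormone expression in the IPC cells is in line with the 35 hormone reads, and remains a hypothesis, since RNA of primary islet cells would bring the same reads and a difference between library batches was not testable with 1 library each.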

How the results depend on the processing

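Totals without the 2 most abundant MSC miRNAs, scaling to the median miRNA, no mismatch beyond position 18, no limit on the 3′ end, and miR-221-5p and miR-222b-3p left out were chosen after seeing the data. With a pseudocount of 5, reads of several matches left out, no mismatch beyond position 18, no limit on the 3′ end, either filter, totals without the most abundant miRNA, and miR-221-5p and miR-222b-3p left out, no named ratio that had been called higher or lower changed sign. Counting all reads within a hairpin, and ribosomal and transfer RNA before miRNAs, was not run because no genome was used. No paired analysis was possible because each cell type has 1 library. Depth limits the ratios that rest on low counts: in the MSC library 21 reads of miR-375-3p, 3 of miR-216b-5p and 0 of miR-216a-5p, and in the shallower IPC library 0 reads of miR-196-5p and 4 each of miR-1b-3p and miR-206-3p.

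The count of miRNAs higher and lower, 77 and 24, became 56 and 42 with scaling to all reads, 50 and 48 with TMM, 53 and 47 with median of ratios, 49 and 49 with totals without the 2 most abundant MSC miRNAs, and 53 and 48 relative to the median miRNA. Totals without the most abundant miRNA gave 64 and 34, and the other settings apart from exact reads gave 71 to 80 higher and 18 to 25 lower. It was 51 and 44 with exact mature reads, where 6 calls were opposite to the main ones. Of the 70 named and called miRNAs, 53 kept their call with exact reads, 5 were opposite (miR-30d-5p, miR-155-5p, miR-1329-5p, miR-363-3p and miR-210-3p) and 12 were not called. Of these 12, miR-153-3p had too few exact reads, and miR-145-5p, miR-133-3p, let-7b, miR-16-5p and miR-301a-3p kept a ratio above 1 but under 2-fold. The opposite call of miR-155-5p rests on 42 exact MSC reads and 2 exact IPC reads. The scalings differ from the main one by 1 factor for all miRNAs, so their construction sets these shifts. The exact-read ratios also move by 1 common factor, because the total becomes that of exact reads. miR-148a-3p, with 87.5% of its MSC and 87.3% of its IPC reads exact, moved from 0.44 to -1.15 on the log2 scale. Beyond that factor an exact-read ratio moves when the share of a miRNA's reads that are exact differs between the libraries. For miR-143-3p this share was 1.62% in the MSC library and 43.8% in the IPC library. What causes the remaining shifts was not tested.

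The islet list's median log2 ratio was 0.30 with all reads, -0.23 with TMM, -0.089 with median of ratios, 0.93 without the most abundant miRNA, -0.32 without the 2 most abundant MSC miRNAs, -0.16 relative to the median miRNA, -0.11 with exact reads and 1.41 with no mismatch beyond position 18. It was 2.64 without a filter and 3.01 at 100 RPM or more, as different members enter. The mesenchymal list's median was 0.34, -0.19, -0.048, 0.97, -0.28, -0.12 and 0.57 under the first 7 of these settings.

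Called ratios of named miRNAs that reversed are given on the log2 scale. Of the named miRNAs within 2-fold, miR-148a-3p, miR-10a-5p and miR-126-3p also went from above 0 to below it, to -0.93, -1.004 and -0.73 with all reads, -1.46, -1.54 and -1.27 with TMM, -1.32, -1.39 and -1.12 with median of ratios, -0.30, -0.38 and -0.11 without the most abundant miRNA, -1.55, -1.63 and -1.36 without the 2 most abundant MSC miRNAs, and -1.39, -1.47 and -1.20 relative to the median miRNA. Exact reads gave -1.15 for miR-148a-3p and -0.85 for miR-10a-5p, and no mismatch beyond position 18 gave -0.032 for miR-126-3p. With all reads, they were -0.011 for miR-30d-5p, -0.17 for miR-146a/c-5p and -0.12 for miR-10b-5p. With TMM, they were -0.55 for miR-30d-5p, -0.71 for miR-146a/c-5p, -0.18 for miR-133-3p, -0.034 for let-7b, -0.65 for miR-10b-5p, -0.26 for miR-210-3p, -0.49 for miR-29b-3p and -0.11 for miR-16-5p. Median of ratios gave -0.40 for miR-30d-5p, -0.56 for miR-146a/c-5p, -0.034 for miR-133-3p, -0.51 for miR-10b-5p, -0.12 for miR-210-3p and -0.34 for miR-29b-3p. Without the 2 most abundant MSC miRNAs they were -0.63 for miR-30d-5p, -0.79 for miR-146a/c-5p, -0.27 for miR-133-3p, -0.12 for let-7b, -0.053 for miR-34a-5p, -0.74 for miR-10b-5p, -0.35 for miR-210-3p, -0.57 for miR-29b-3p and -0.20 for miR-16-5p. Relative to the median miRNA they were -0.47 for miR-30d-5p, -0.63 for miR-146a/c-5p, -0.11 for miR-133-3p, -0.58 for miR-10b-5p, -0.19 for miR-210-3p, -0.41 for miR-29b-3p and -0.038 for miR-16-5p. Exact mature reads gave -1.91 for miR-30d-5p, -0.31 for miR-146a/c-5p, -3.66 for miR-155-5p, -0.37 for miR-456-3p, -1.33 for miR-1329-5p, -0.13 for let-7i, -1.29 for miR-363-3p, -0.19 for miR-34a-5p, -0.21 for miR-10b-5p, -1.94 for miR-210-3p and -0.51 for miR-29b-3p.

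The share of reads at 21 to 23 nt was 13.0% for MSC and 23.1% for IPC when distinct sequences were counted, opposite in order to the shares of reads, and 48.0% and 34.8% without sequences seen once. The miRNA share was 56.2% and 21.6% with 1 mismatch allowed, and 56.3% and 22.4% without sequences seen once.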

Other observations

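The arms, their miRNAs and the RNA classes in this part, and the tests of both patterns below, were chosen after the results had been seen. The share of reads from the 5p and 3p arms of a precursor differed between the libraries, a ratio within each library that no scaling changes. For miR-142 the 5p arm made up 8.88% of reads from both arms in the MSC library (7.47 to 10.4) and 93.8% in the IPC library. For miR-126 it was 27.4% (23.8 to 31.1) and 74.5% (71.0 to 77.8). All reads of its 3p arm differed from the written sequence (0 exact reads in either library), while the 5p arm had 53 and 423. The miR-126 difference therefore rests on reads that are not exact. For miR-22 the 5p arm made up 11.2% and 0.0559%, and for miR-30e it was 65.2% and 87.4%. miR-9 differed little, at 87.2% and 90.8% with overlapping intervals. The 3′ ends counted are those of the written table, so an arm whose ends lie elsewhere can be undercounted, by a different amount in each library. Of the miR-126-5p reads, 32.7% were exact in the MSC library and 87.8% in the IPC library.

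Within the glycine transfer RNA fragments, a form lacking 1 G took 3.96% of MSC reads and 0.0568% of IPC reads. A panel of 10 miRNAs found in mammals but not known from chicken had 2 reads in the MSC library and 8 in the IPC library. Part of the 5′ sequencing adapter was in 0.187% of MSC reads and 0.0215% of IPC reads.

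Most miRNAs were higher in the IPC library when scaled to the miRNA total. miR-143-3p and miR-21-5p took 49.3% and 28.7% of miRNA reads in the MSC library, against 1.02% and 11.4% in the IPC library. Shares add up to the whole, so the summed share of all other miRNAs was higher in the IPC library by arithmetic. Whether this accounts for the ratio of each single miRNA stays open. With the most abundant miRNA of each library left out of its total, the median log2 ratio of the tested miRNAs was 1.09, against 1.83 by the main counting. It was -0.16 with miR-143-3p and miR-21-5p left out of both totals, but that setting lowers every ratio by construction and decides nothing. Whether the amount of miRNA per cell differed stays open too, since shares of reads carry no absolute amount.

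miR-1a-3p stood at 5312 RPM in the MSC library, and skeletal or heart muscle cells in that culture are a candidate source. miR-133, which is made from the same transcripts in muscle, reached 1.04% of the miR-1 reads there, while 539 reads of miR-206-3p and 425 of miR-499-5p, both muscle miRNAs, were present. These values do not decide the matter, since adapter ligation may favour 1 miRNA over another, and expression of miR-1 in the MSC themselves stays open as well.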
